A study of Saccharomyces cerevisiae with 17 samples.

How the data were processed

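RNA-seq of 8 yeast libraries and FLAG ChIP-seq of 9 libraries were analysed from processed files. Per the labels, RNA was depleted of ribosomal RNA and sequenced single-end from a directional kit. The deposited RNA files hold raw read counts per open reading frame, 1 file per library, made with cutadapt, TopHat and HTSeq on the R64 genome per the submitters' processing notes. The HTSeq strand setting is not given in the sources used here. Reads from near-identical copies and overlapping genes are therefore uncertain, and 53.5 to 65.3% of all HTSeq lines per library were alignments that were not unique. The 5 HTSeq total lines were left out. Reads outside genes made 23.4 to 37.5% of reads in and outside genes, and ambiguous reads at most 0.0890% of all lines.

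The deposited ChIP table holds mean and maximum signal per peak for each of 9 libraries, headed by the authors as RPKM and RPM but used here as signal, since the values behave as read depth scaled to a common library. The authors' fold enrichment ratio divides the mean signal of a precipitate by that of the total extract of the same construct, per the file headers, and recomputing it gave the same ratio to within 2.5e-09. Peaks come from cutadapt and Bowtie 1.1.2 on R64 per the submitters' processing notes, and the peak caller and any pooling are not given in the sources used here. The letters a and b of precipitates are not tied to separate cultures by the labels. The ChIP growth labels give a different number of biological replicates for each library. The order of peaks by mean Brr6N fold was computed here.

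Of 6572 feature IDs, 5898 matched the gene table of R64, and the other 674 kept their systematic names. Genes passed edgeR's filterByExpr with a minimum count of 10, which left 6297. Counts were scaled by TMM and fitted by edgeR's quasi-likelihood method with all 8 libraries and 4 groups in 1 model, with 4 residual degrees of freedom. The 5 comparisons are brr6-1 against WT in each medium, galactose against glucose in each strain, and the difference of the brr6-1 effect between media. Adjusted p is Benjamini-Hochberg within each comparison, with a threshold of 0.05. Of 36 gene lists, written before the data were examined along with the design, comparisons and most alternatives, 31 were tested with camera at a preset correlation of 0.01. The others were 4 lists with fewer than 5 tested members and a list of auxotrophic marker loci, which was set aside in advance as a check of the labels. Camera with an estimated correlation and fry, which tests a list alone, were alternatives. Statistics used R 4.3.3, edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0, and tables and plots used Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.

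Genes named in the report follow a rule of fixed parts. These are BRR6, BRL1, APQ12, LEU2, HIS3, GAL1, GAL7, GAL10 and GAL2, then the 8 largest rises and 8 largest falls with no overlap between the libraries of the groups (5 each way for the media and for the difference), then per list up to 4 members that passed and up to 2 that did not, and genes at the 10 highest peaks. Not every gene the rule allows is printed. PDE1 and RAI1 are listed at the BRR6 peak, and AGA1 is named for its peak outside the rule. Genes with few counts are given with an exact 95% counting interval or a floor of 3 counts over the group, which cover counting error and no other variation. In data simulated from the same means and depths, 68 of the 6221 genes run were changed by 2-fold for brr6-1 in glucose, and 82.4% of these were called. Called likewise were 76.7% of 60 genes in galactose (6206 run) and 76.5% of 68 between media in WT (6213 run). Of 60 genes each, 81.7% were called between media in brr6-1 and 51.7% for the difference (6206 run each). At 1.5-fold these were 29.5, 27.3, 30.4, 27.3 and 5.19%. False calls made up 7.14, 7.19, 5.06, 5.30 and 6.80% of all calls in the same order, against the 5% aimed at. The simulations changed fewer genes than were called in the data, with no trend by abundance or chromosome. How far these rates carry over to the data was not tested.

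Alternatives were DESeq2 size factors or library totals alone as scaling, no filter or at least 100 counts in each of 2 libraries, DESeq2's Wald test, robust empirical Bayes, a replicate block, only the 4 libraries compared, and each library left out in turn. Added after the data were seen were cyclic loess in limma-voom, removal of chromosome III genes, removal of unmatched features, and peak genes without those at BRR6 and on chromosome III. A call kept its status where direction and side of the threshold held, and a change of sign in a value that passed neither way counted as the same. Peaks were compared as the authors list them, with a construct called above another where both its folds exceeded both of the other's.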

Results

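The series holds 8 RNA-seq libraries of budding yeast and the FLAG chromatin immunoprecipitation (ChIP) signal of 9 further libraries at 22 peaks. RNA came from the wild-type strain YPH399 (WT) and from a brr6-1 strain, whose BRR6 gene carries an arginine-to-lysine change in a putative zinc finger of Brr6, a membrane protein of the nuclear envelope. Glucose cultures held 2% of that sugar. Galactose cultures grew on raffinose (2%) plus sucrose (0.04%) before 2 h in galactose (2%). Each of the 4 groups has 2 biological replicates, A and B. Gene counts per library ran from 15059271 to 21637381, and log2 CPM (counts scaled to a common library size) of libraries of 1 group correlated at 0.988 to 0.995 across genes. Values below are log2 fold changes ± standard error from the fit to all 8 libraries, with n = 2 libraries per group. That standard error was computed as the absolute log2 fold change over the square root of the quasi-likelihood F. Adjusted p is Benjamini-Hochberg adjusted from edgeR's quasi-likelihood test for genes and from camera for gene groups.

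The targeted gene was read first. BRR6 stood at 28.0 and 29.5 CPM in the WT glucose libraries and at 98.5 and 103 CPM in the brr6-1 glucose libraries. In galactose it stood at 24.4 and 19.1 CPM in WT and at 216 and 169 CPM in brr6-1. The transcript was thus higher in the mutant in both media, by 1.81 ± 0.16 in glucose (adjusted p = 1.3e-04) and by 3.14 ± 0.17 in galactose (adjusted p = 5.9e-06). The point mutation itself cannot be read from counts per gene. PDE1, a cyclic AMP phosphodiesterase gene that ends next to the start of BRR6 on chromosome VII (35653 to 36762, with BRR6 at 36933 to 37526, R64), was higher by 2.64 ± 0.16 and 3.39 ± 0.16. RAI1, on the other side at 37617 to 38780, was higher in galactose (0.81 ± 0.13) and had -0.01 ± 0.13 in glucose (adjusted p = 0.972). The allele carries LEU2 and HIS3 as markers per the labels. HIS3 had 0 counts in both WT glucose libraries against a mean of 31.0 ± 17.5 CPM (SD, n = 2) in brr6-1, at least 342-fold higher when the floor is 3 counts over the group. In galactose WT had 6 and 3 counts, and HIS3 was higher by 6.08 ± 0.55 in brr6-1. LEU2 was higher by 2.27 ± 0.19 in glucose and 2.54 ± 0.19 in galactose. BRL1 and APQ12, whose products work with Brr6 in the nuclear envelope, were higher in galactose (0.46 ± 0.13 and 1.03 ± 0.27). In glucose they had -0.06 ± 0.13 (adjusted p = 0.728) and 0.52 ± 0.28 (adjusted p = 0.159), and the difference between media did not pass for either gene (adjusted p = 0.111 and 0.449). BRL1 (adjusted p = 0.0987) no longer passed without WT galactose replicate A. APQ12 (adjusted p = 0.0839) no longer passed without WT galactose replicate B. APQ12 (adjusted p = 0.129) and BRL1 (0.169) no longer passed without brr6-1 galactose replicate A. APQ12 (adjusted p = 0.0975) and BRL1 (0.0899) no longer passed without brr6-1 galactose replicate B. Under cyclic loess, APQ12 (adjusted p = 0.0824) no longer passed. With only the 4 libraries compared, APQ12 (adjusted p = 0.0534) and BRL1 (0.0561) no longer passed.

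In glucose, the comparison asks which transcripts differ between the brr6-1 strain and WT in the repressing sugar. The strains also differ in the LEU2 and HIS3 markers and in transcripts of chromosome III. A change is therefore not tied to Brr6 alone. Genes of the response to phosphate starvation fell. Of 20 tested, 16 fell and 1 rose (16 and 1 adjusted over the list alone), with PHO84 (-5.36 ± 0.27) and PHO89 (-2.95 ± 0.33), transporters of phosphate. Also lower were SPL2 (-5.01 ± 0.29), a regulator of low-affinity uptake, PHO12 (-4.63 ± 0.22), an acid phosphatase nearly identical to PHO11 (-2.86 ± 0.20), and VTC3 (-3.50 ± 0.15), a subunit of the polyphosphate polymerase. Values of PHO11 and PHO12 are therefore uncertain, here and below. PPN1 and KCS1 did not pass (-0.25 ± 0.14 and -0.12 ± 0.12). The group as a whole had a median of -1.58 (adjusted p = 1.1e-36, and adjusted p = 0.00445 with an estimated correlation, where the call holds). Iron uptake genes shifted downward as a group. Of these, 1 of 30 rose and 19 fell (1 and 21 adjusted over the list alone; adjusted p = 1.4e-10, and adjusted p = 0.323 with an estimated correlation). Those that fell include FET3 (-3.30 ± 0.28), a multicopper ferroxidase, FTR1 (-2.02 ± 0.22), its permease partner, TIS11 (-2.19 ± 0.36) and SIT1 (-1.68 ± 0.29).

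Ribosomal protein, ribosome biogenesis and glycolysis genes shifted downward as groups in brr6-1 in glucose. Of the cytosolic ribosomal protein genes, 1 of 137 rose and 94 fell (1 and 97 adjusted over the list alone), with a median of -0.58 (adjusted p = 2.8e-17, and adjusted p = 0.444 with an estimated correlation). RPS20 (-1.65 ± 0.26) and RPL22A (-1.39 ± 0.27) were among them. In ribosome biogenesis 2 of 91 rose and 30 fell (2 and 29 adjusted over the list alone), with a median of -0.31 (adjusted p = 1.3e-04, and adjusted p = 0.596 with an estimated correlation). Of these genes BRX1 (-1.16 ± 0.20) and NSR1 (-1.05 ± 0.21) fell. Of the glycolytic genes 0 of 20 rose and 10 fell (2 and 12 adjusted over the list alone), with TDH1 (-2.15 ± 0.26), a glyceraldehyde-3-phosphate dehydrogenase, ENO1 (-1.55 ± 0.20), an enolase, and CDC19 (-1.28 ± 0.25), pyruvate kinase. The glycolysis group gave adjusted p = 7.4e-05, and adjusted p = 0.323 with an estimated correlation. PGK1, a glycolytic gene on chromosome III, had 0.23 ± 0.16 (adjusted p = 0.274). In the proteasome 1 of 33 rose and 17 fell (1 and 19 adjusted over the list alone; adjusted p = 1.2e-05, and adjusted p = 0.341 with an estimated correlation). In ergosterol synthesis 0 of 24 rose and 13 fell (0 and 14 adjusted over the list alone; adjusted p = 2.1e-04, and adjusted p = 0.539 with an estimated correlation). Among the genes of these groups that fell were PUP1 (-1.10 ± 0.15) and ERG10 (-1.06 ± 0.18). Under cyclic loess scaling, the median of glycolysis was -0.10 in place of -0.60, that of ribosomal proteins -0.36 in place of -0.58 and that of ribosome biogenesis -0.17. For the proteasome it was -0.27 in place of -0.44 and for ergosterol synthesis -0.28 in place of -0.50. Tested alone, ribosome biogenesis had an adjusted p of 0.147 and ergosterol synthesis 0.0572. LEU1, a leucine synthesis enzyme, fell as well (-3.00 ± 0.19). The strains also differ in the LEU2 marker, whose effect on LEU1 cannot be told apart from that of brr6-1. NSR1 (adjusted p = 0.0501) no longer passed without WT glucose replicate B.

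Groups of sporulation, hypoxia and cell wall genes shifted upward in brr6-1 in glucose. Of the meiosis and sporulation genes, 22 of 33 rose and 0 fell (28 and 0 adjusted over the list alone), among them SPS2 (3.34 ± 0.64), IME4 (2.31 ± 0.69) and SPO75 (2.29 ± 0.43), with a median of 1.20 (adjusted p = 1.0e-08, and adjusted p = 0.341 with an estimated correlation). In the hypoxia and membrane fluidity group 13 of 27 rose and 2 fell (14 and 3 adjusted over the list alone; adjusted p = 2.3e-04, and adjusted p = 0.323 with an estimated correlation). Here DAN1 (3.46 ± 0.51) and TIR1 (2.68 ± 0.52), cell wall mannoproteins of anaerobic growth, rose, as did ELO2 (1.45 ± 0.12), a fatty acid elongase on chromosome III. In cell wall integrity 13 of 34 rose and 0 fell (13 and 0 adjusted over the list alone), with MTL1 (1.65 ± 0.40) and PIR3 (1.18 ± 0.34). The cell wall integrity group gave adjusted p = 0.00432, and adjusted p = 0.341 with an estimated correlation. Members of the PAU and COS families at chromosome ends, which share reads with near-identical copies and are uncertain, rose in 5 of 15 cases (5 adjusted over the list alone; adjusted p = 0.00186, and adjusted p = 0.323 with an estimated correlation), with COS12 (1.96 ± 0.28). Of the genes that others have placed at the nuclear periphery on induction, 8 of 20 rose and 1 fell (9 and 1 adjusted over the list alone; adjusted p = 0.00502, and adjusted p = 0.323 with an estimated correlation). They include FIG2 (2.51 ± 0.45), FUS1 (2.45 ± 0.34) and HSP30 (2.18 ± 0.29), all on chromosome III, and STL1 (2.29 ± 0.58), a glycerol transporter. Without chromosome III genes the group's adjusted p was 0.0748. Other genes with large rises were GEX1 (3.48 ± 0.81) and FRM2 (2.71 ± 0.48), both on chromosome III, and ECM8 (2.66 ± 0.63). HMRA1, a silent mating-type gene on chromosome III, had 24 counts over both brr6-1 libraries and 3 over both WT libraries, a ratio of 8.03 with a 95% exact counting interval of 2.44 to 41.6. In the general stress group 18 of 60 rose and 3 fell (18 and 3 adjusted over the list alone; adjusted p = 0.00557, and adjusted p = 0.539 with an estimated correlation). It holds XBP1 (2.03 ± 0.55) and GRE2 (-1.82 ± 0.28). Its adjusted p was 0.0584 without brr6-1 glucose replicate B and 0.0811 when the group was tested alone. Hexose transporters and glucose-repressed carbon genes shifted upward as groups. Of the former 6 of 15 rose and 1 fell (7 and 2 adjusted over the list alone; adjusted p = 0.0473, and adjusted p = 0.539 with an estimated correlation), and of the latter 11 of 29 rose and 5 fell (15 and 6 adjusted over the list alone; adjusted p = 0.0241, and adjusted p = 0.539 with an estimated correlation). Without brr6-1 glucose replicate A their adjusted p was 0.297 and 0.175, tested alone it was 0.121 and 0.100, and under library totals alone that of hexose transporters was 0.225. Under cyclic loess the medians of meiosis and sporulation, the PAU and COS families, hexose transporters and glucose-repressed genes were 0.73, 0.32, 0.47 and 0.38, in place of 1.20, 1.00, 0.89 and 0.59. Nuclear pore genes were not shifted as a group (median 0.10, adjusted p = 0.234), and neither was the GAL regulon (adjusted p = 0.640). GEX1 (adjusted p = 0.0818), IME4 (0.124), MTL1 (0.0759), PIR3 (0.150), SPS2 (0.0535), STL1 (0.0690), TIR1 (0.0525) and XBP1 (0.0781) no longer passed without WT glucose replicate A. ECM8 (adjusted p = 0.103), GEX1 (0.0676), IME4 (0.144), MTL1 (0.0891), PIR3 (0.0964), SPO75 (0.0505), STL1 (0.106), TIR1 (0.0534) and XBP1 (0.130) no longer passed without WT glucose replicate B. GEX1 (adjusted p = 0.0624), IME4 (0.143), STL1 (0.0965) and XBP1 (0.110) no longer passed without brr6-1 glucose replicate A. PIR3 (adjusted p = 0.0779) no longer passed without brr6-1 glucose replicate B. Under cyclic loess, IME4 (adjusted p = 0.0779), MTL1 (0.0813), PIR3 (0.390), STL1 (0.0612) and XBP1 (0.0672) no longer passed.

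In all, 1050 genes rose and 1230 fell in glucose out of 6297 tested, 426 and 115 of them by at least 2-fold. Of the 159 tested genes of chromosome III, 133 rose and 0 fell. On that chromosome lie 4 of the genes recruited to the periphery, 2 of the hypoxia genes and 2 of the glycolytic genes. Among the 1014 genes under 2 log2 CPM, 218 rose and 5 fell, with a median of 1.20, against -0.08 for the other 5283 genes. Of the gene groups above, meiosis and sporulation (median 2.3 log2 CPM) and the PAU and COS families (1.9) lie in or near that range. At the other end, 356 of the 872 genes over 8 log2 CPM outside chromosome III fell and 56 rose, with a median of -0.33. In that range lie the medians of glycolysis (10.8), ribosomal proteins (8.2), the proteasome (8.2) and ergosterol synthesis (8.4). Scaling by library totals alone moved the median of all genes by 0.32, and 86.5% rather than 46.1% of the calls were then higher. The count of 2280 was 636 without WT glucose replicate A, 516 without WT glucose replicate B and 1143 without brr6-1 glucose replicate A.

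**Figure D1:**
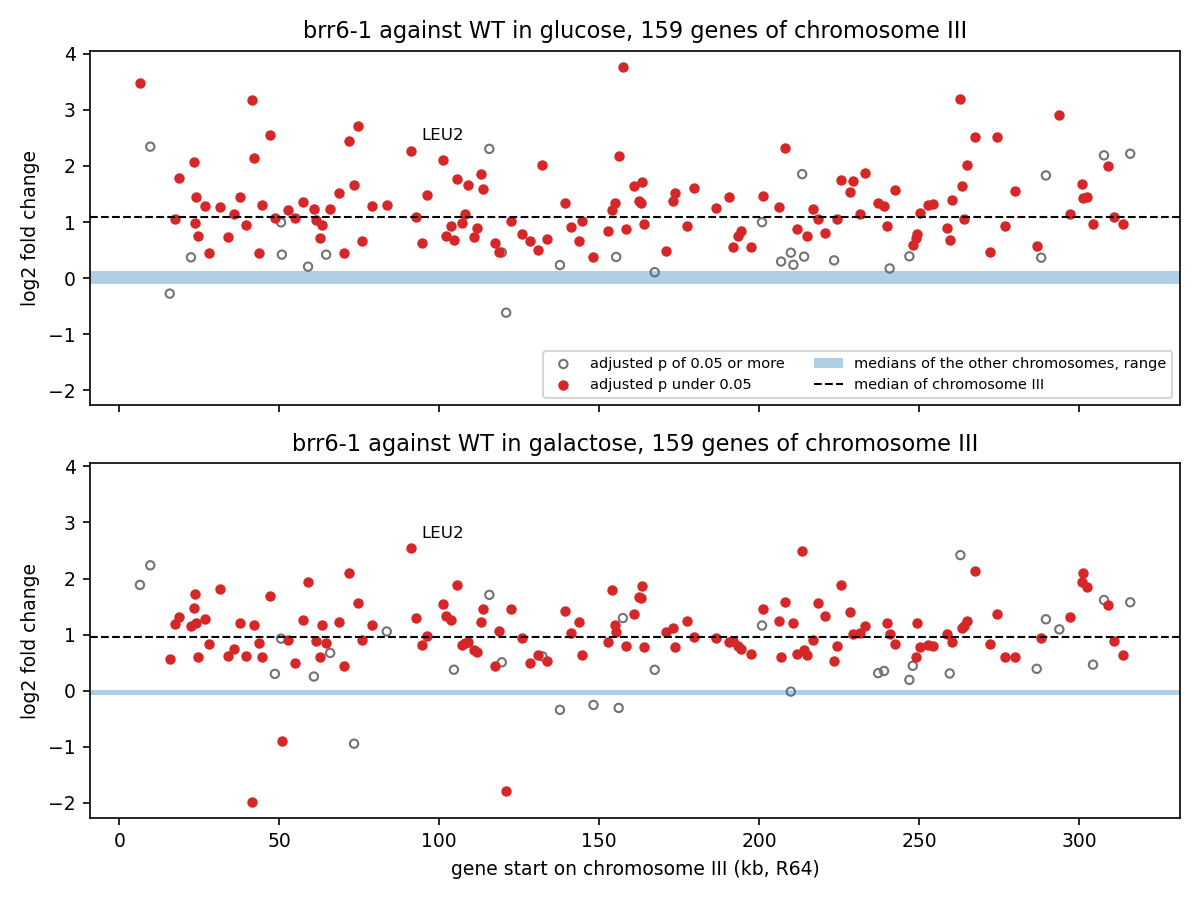
Log2 fold change of brr6-1 against WT for the 159 tested genes of chromosome III by gene start in kb (R64), in glucose (upper panel) and galactose (lower panel). Filled points passed the gene test, the dashed line is the median of the chromosome (1.08 and 0.96) and the shaded band is the range of the medians of the other 15 nuclear chromosomes.

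In galactose, the same strains were compared 2 h after induction, when GAL genes are recruited to the nuclear periphery. Glycolytic genes fell. Of these, 0 of 20 rose and 17 fell (0 and 17 adjusted over the list alone), with TDH1 (-5.81 ± 0.30), ENO1 (-3.13 ± 0.21), CDC19 (-2.02 ± 0.26) and GPM1 (-2.00 ± 0.16). PGK1 had -0.34 ± 0.16 (adjusted p = 0.158). Their median was -1.23 (adjusted p = 7.3e-25, and adjusted p = 0.0255 with an estimated correlation, where the call holds). General stress genes shifted downward as a group. Here 0 of 60 rose and 38 fell (1 and 41 adjusted over the list alone; adjusted p = 9.0e-20, and adjusted p = 0.255 with an estimated correlation). They include HSP26 (-3.57 ± 0.26), a small heat shock protein, HSP12 (-2.44 ± 0.18), a membrane stress protein, GRE2 (-3.15 ± 0.29) and TSL1 (-1.94 ± 0.26), a subunit of trehalose synthase. ADH2 (-3.27 ± 0.32), the glucose-repressed alcohol dehydrogenase, and OYE3 (-3.80 ± 0.47), an NADPH oxidoreductase, fell too.

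Phosphate and iron genes shifted downward as groups in this medium too. Of the phosphate starvation genes 1 of 20 rose and 15 fell (2 and 15 adjusted over the list alone), with PHO84 (-3.94 ± 0.25), PHO89 (-3.82 ± 0.32), PHM8 (-2.36 ± 0.14) and SPL2 (-2.13 ± 0.26). The phosphate starvation group gave adjusted p = 7.8e-19, and adjusted p = 0.0176 with an estimated correlation, where the call holds. Of the iron genes 1 of 30 rose and 22 fell (1 and 23 adjusted over the list alone; adjusted p = 6.6e-13, and adjusted p = 0.316 with an estimated correlation). These include FIT2 (-3.63 ± 0.36) and FIT3 (-3.04 ± 0.35), cell wall proteins that hold siderophores, and TIS11 (-2.46 ± 0.30) and ARN1 (-2.18 ± 0.14). Sulfur and methionine genes fell in 13 of 30 cases and rose in 0 (16 and 0 adjusted over the list alone), with MET2 (-2.21 ± 0.24) and MET17 (-1.49 ± 0.26). The sulfur and methionine group gave adjusted p = 2.1e-06, and adjusted p = 0.371 with an estimated correlation. The drug resistance regulon had 9 of 19 lower and 0 higher (10 and 0 adjusted over the list alone), with FLR1 (-1.45 ± 0.31) and PDR15 (-1.37 ± 0.19). The pleiotropic drug resistance group gave adjusted p = 0.00242, and adjusted p = 0.409 with an estimated correlation. In cell wall integrity 1 of 34 rose and 12 fell (2 and 14 adjusted over the list alone), with GSC2 (-1.41 ± 0.16), a glucan synthase subunit. The cell wall integrity group gave adjusted p = 0.00793, and adjusted p = 0.409 with an estimated correlation. FLR1 (adjusted p = 0.0993) and MET17 (0.0534) no longer passed without brr6-1 galactose replicate A.

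Of the 12 tested genes of the GAL regulon, 5 fell, 1 rose and 6 did not pass. GAL1 stood at 15268 ± 2707 CPM (SD, n = 2) in WT and 8591 ± 1329 CPM in brr6-1. Of the GAL genes fixed in advance, GAL7 fell (-0.81 ± 0.21, adjusted p = 0.020), while GAL1 (-0.83 ± 0.31, adjusted p = 0.0784), GAL10 (-0.70 ± 0.30, adjusted p = 0.118) and GAL2 (-0.70 ± 0.36, adjusted p = 0.179) did not pass. Adjusted over the list alone, 6 fell and 1 rose. The group test pointed down (adjusted p = 0.0338, and adjusted p = 0.523 with an estimated correlation). Members that passed include PGM2 (-1.61 ± 0.20), phosphoglucomutase, GAL3 (-1.01 ± 0.13), the galactose sensor, GAL80 (-0.91 ± 0.21), the repressor, and FUR4 (1.90 ± 0.16), a uracil permease next to GAL1. That shift of the group was lost without WT galactose replicate B (adjusted p = 0.109) and with the group tested alone (adjusted p = 0.0689). Of the genes recruited to the periphery, 2 of 20 rose and 7 fell (2 and 8 adjusted over the list alone), with HXK1 (-1.67 ± 0.17), FIG2 (2.14 ± 0.42) and FUS1 (2.10 ± 0.33), the latter pair on chromosome III. The group of genes recruited to the nuclear periphery gave adjusted p = 0.0125, and adjusted p = 0.313 with an estimated correlation. That p was 0.0906 without WT galactose replicate A. For hexose transporters 1 of 15 rose and 6 fell (2 and 6 adjusted over the list alone), with HXT7 (-2.15 ± 0.21), HXT2 (-1.15 ± 0.27) and HXT14 (1.60 ± 0.47). Their median was 0.64 and their mean -0.18, and the group test pointed down (adjusted p = 0.479). HXT6 and HXT7 are nearly identical, so both are uncertain. HXT6 had 1 count over both brr6-1 libraries and 36 over both WT libraries (ratio 34.0 with a 95% exact counting interval of 5.72 to 1379 in favour of WT). GAL7 (adjusted p = 0.0864), GAL80 (0.0987), HXT14 (0.0849) and HXT2 (0.0820) no longer passed without WT galactose replicate B. GAL7 (adjusted p = 0.0919), GAL80 (0.120), HXT14 (0.237) and HXT2 (0.0550) no longer passed without brr6-1 galactose replicate A. GAL7 (adjusted p = 0.118), GAL80 (0.0524), HXT14 (0.0569) and HXT2 (0.0960) no longer passed without brr6-1 galactose replicate B. With only the 4 libraries compared, HXT14 (adjusted p = 0.0675) no longer passed.

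Ribosome biogenesis genes shifted upward as a group in galactose. Here 24 of 91 rose and 0 fell (24 and 0 adjusted over the list alone), with PWP2 (1.33 ± 0.16), a gene on chromosome III, and KRR1 (1.15 ± 0.21), on chromosome III as well. The ribosome biogenesis group gave adjusted p = 3.1e-05, and adjusted p = 0.579 with an estimated correlation. Its adjusted p was 0.120 without WT galactose replicate A. Cytosolic ribosomal protein genes shifted downward as a group, and 4 of 137 rose and 40 fell (6 and 51 adjusted over the list alone; adjusted p = 0.00124, and adjusted p = 0.617 with an estimated correlation). Their median was -0.31, and -0.15 under cyclic loess. RPS20 had -1.14 ± 0.26 and RPS14A, on chromosome III, 1.24 ± 0.18. Without WT galactose replicate B, the adjusted p of ribosomal protein genes was 0.338. Tested alone, the biogenesis and ribosomal protein groups had an adjusted p of 0.162 and 0.158. Other genes with large rises were SAE3 (2.90 ± 0.82), COS12 (2.88 ± 0.34), ECM23 (2.18 ± 0.65) and ANS1 (2.16 ± 0.69). In all, 522 genes rose and 901 fell, 174 and 250 by at least 2-fold. Of the 159 chromosome III genes 125 rose and 3 fell, and genes under 2 log2 CPM had a median of 0.76 (67 rose, 10 fell). Over 8 log2 CPM outside chromosome III, 204 fell and 58 rose, with a median of -0.12. Library totals alone moved the median of all genes by 0.24, with 75.0% of calls higher instead of 36.7%. The count of 1423 was 724 without WT galactose replicate B, 423 without brr6-1 galactose replicate A and 720 without brr6-1 galactose replicate B. ANS1 (adjusted p = 0.0723) and SAE3 (0.0623) no longer passed without WT galactose replicate A. ANS1 (adjusted p = 0.120), ECM23 (0.121) and SAE3 (0.0860) no longer passed without WT galactose replicate B. ANS1 (adjusted p = 0.140), ECM23 (0.172), KRR1 (0.0514), RPS20 (0.0981) and SAE3 (0.119) no longer passed without brr6-1 galactose replicate A. ANS1 (adjusted p = 0.242), ECM23 (0.142), RPS20 (0.0609) and SAE3 (0.131) no longer passed without brr6-1 galactose replicate B. In DESeq2, ANS1 (adjusted p = 0.0931) no longer passed. Under cyclic loess, ANS1 (adjusted p = 0.401), ECM23 (0.105) and SAE3 (0.272) no longer passed. With only the 4 libraries compared, ANS1 (adjusted p = 0.0775), ECM23 (0.0583) and SAE3 (0.0563) no longer passed. Without chromosome III genes, ANS1 (adjusted p = 0.0505) no longer passed.

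Effects in the 2 media were set against each other. Across all 6297 tested genes, which are not independent replicates, fold changes correlated at r = 0.629 (Spearman's rho 0.597). In all, 250 genes rose in both media (87.0 expected from independent lists), 440 fell in both (176 expected) and 51 went opposite ways. Without chromosome III, r was 0.616 and 137 rose in both (59.3 expected). Among the 4371 genes over 4 log2 CPM r was 0.514, and 0.457 without chromosome III, where 65 rose in both (26.8 expected). With 1 library left out, r ran from 0.447 (WT galactose replicate B) to 0.707 (WT galactose replicate A).

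The difference of the brr6-1 effect between media was tested directly as an interaction. Among phosphate genes PHO12 (3.12 ± 0.31), SPL2 (2.88 ± 0.41) and PHO11 (2.19 ± 0.29) had fallen more in glucose, as had FET3 (1.77 ± 0.36). PHO11 and PHO12 are nearly identical, so both are uncertain. CYC1 (1.87 ± 0.47), cytochrome c, had a higher log2 fold change in galactose than in glucose. Stress and carbon genes differed the other way, among them OYE3 (-3.67 ± 0.68), TDH1 (-3.66 ± 0.36), SPG4 (-3.37 ± 0.56), HSP26 (-3.24 ± 0.35) and GSY1 (-3.20 ± 0.36). In the general stress group 28 of 60 were lower in galactose relative to glucose and 0 higher (45 and 0 adjusted over the list alone; adjusted p = 2.2e-36, and adjusted p = 0.0704 with an estimated correlation). Glycolytic genes shifted the same way, with 8 of 20 lower and 0 higher (14 and 0 adjusted over the list alone; adjusted p = 1.1e-10, and adjusted p = 0.0704 with an estimated correlation). Ribosome biogenesis had 8 of 91 higher and 0 lower (46 and 0 adjusted over the list alone; adjusted p = 1.6e-19, and adjusted p = 0.436 with an estimated correlation), and the group tested alone had an adjusted p of 0.136. Of all genes, 104 were higher and 248 lower in this test. The count of 352 was 606 in DESeq2, 26 without WT glucose replicate A, 3 without WT glucose replicate B, 194 and 816 without WT galactose replicates A and B, and 60 and 152 without brr6-1 galactose replicates A and B. CYC1 (adjusted p = 0.0563) and FET3 (0.0584) no longer passed without WT galactose replicate A. CYC1 (adjusted p = 0.0735) no longer passed without WT galactose replicate B. CYC1 (adjusted p = 0.207), FET3 (0.126), OYE3 (0.107) and SPG4 (0.0875) no longer passed without WT glucose replicate A. CYC1 (adjusted p = 0.168), FET3 (0.0851), GSY1 (0.0518), HSP26 (0.0518), OYE3 (0.130), PHO11 (0.0527), SPG4 (0.0939), SPL2 (0.0678) and TDH1 (0.0518) no longer passed without WT glucose replicate B. CYC1 (adjusted p = 0.151), FET3 (0.0749) and OYE3 (0.0909) no longer passed without brr6-1 galactose replicate A. CYC1 (adjusted p = 0.112), FET3 (0.0762) and OYE3 (0.0509) no longer passed without brr6-1 galactose replicate B. CYC1 (adjusted p = 0.0504) no longer passed without brr6-1 glucose replicate A. In DESeq2, CYC1 (adjusted p = 0.0715) no longer passed. With DESeq2 size factors, CYC1 (adjusted p = 0.0520) no longer passed. Under library totals alone, CYC1 (adjusted p = 0.0641) no longer passed. Under cyclic loess, OYE3 (adjusted p = 0.0636) and SPG4 (0.0619) no longer passed. With a replicate block, CYC1 (adjusted p = 0.0583) no longer passed. With robust empirical Bayes, CYC1 (adjusted p = 0.0790) and OYE3 (0.0577) no longer passed.

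**Figure D2:**
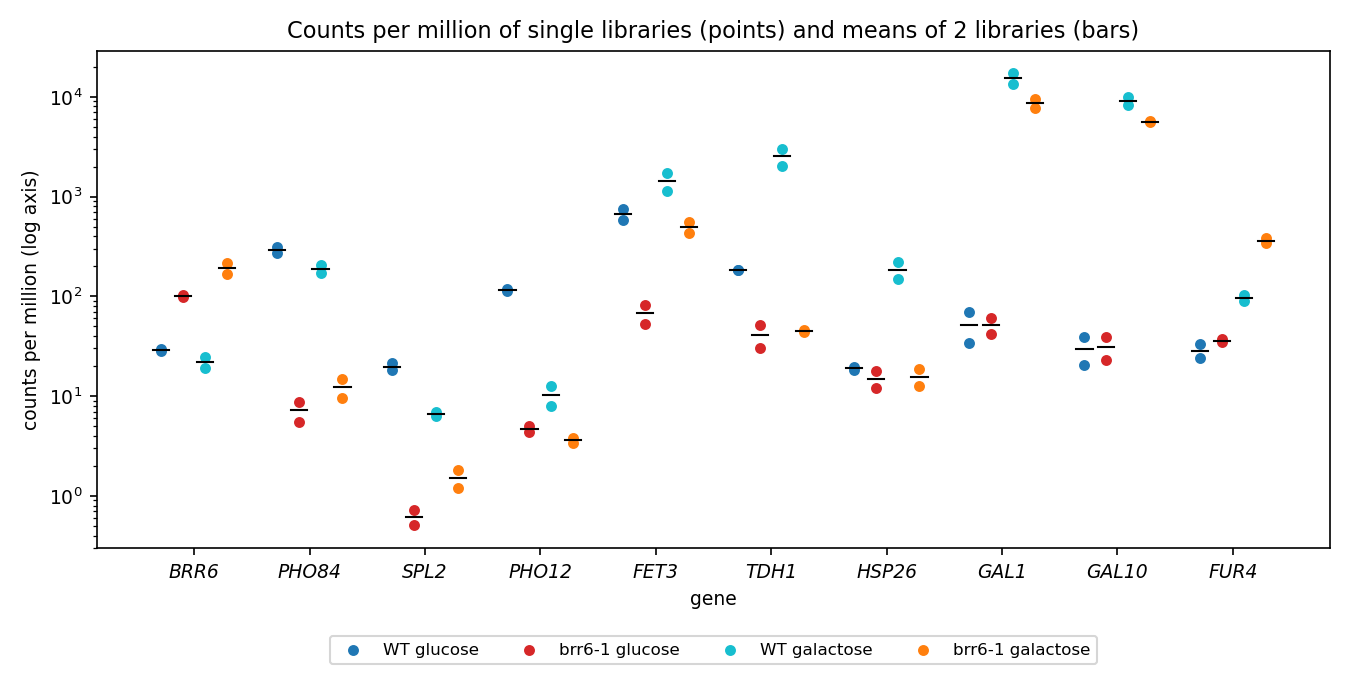
CPM of the 8 RNA libraries for 10 named genes on a log axis. Points are single libraries in the colour of their group and short bars are means of 2 libraries; BRR6 stands higher in both brr6-1 groups and TDH1 lower.

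The medium comparison in WT sets cells given galactose after raffinose plus sucrose against cells in glucose. No group had raffinose without galactose, so galactose cannot be told apart from the absence of glucose. All 12 genes of the GAL regulon rose, among them GAL2 (8.30 ± 0.49), GAL10 (8.26 ± 0.41), GAL1 (8.20 ± 0.42) and GAL7 (7.88 ± 0.29), the transporter and the enzymes of galactose breakdown. The regulon gave adjusted p = 3.6e-40, and adjusted p = 0.0248 with an estimated correlation, where the call holds. Glucose-repressed carbon genes rose in 28 of 29 cases and fell in 0 (28 and 0 adjusted over the list alone), with JEN1 (6.86 ± 0.27), the lactate transporter, ADH2 (5.95 ± 0.38), CYB2 (5.56 ± 0.30) and HXK1 (5.27 ± 0.20). The group of glucose-repressed carbon genes gave adjusted p = 3.1e-35, and adjusted p = 0.0485 with an estimated correlation, where the call holds. MDH2 had 0.05 ± 0.19 (adjusted p = 0.846). All 32 respiratory chain genes rose, with QCR10 (2.81 ± 0.32) and COX5A (2.68 ± 0.21). The respiratory chain group gave adjusted p = 7.1e-30, and adjusted p = 0.0886 with an estimated correlation. Of 15 genes of the TCA cycle, 14 rose, with SDH1 (3.10 ± 0.18). The TCA cycle group gave adjusted p = 5.1e-13, and adjusted p = 0.0509 with an estimated correlation. General stress genes rose in 55 of 60 cases, with RGI2 (6.62 ± 0.55) and TMA10 (6.07 ± 0.20). The general stress response group gave adjusted p = 1.2e-31, and adjusted p = 0.0623 with an estimated correlation. Ribosomal protein genes fell in 108 of 137 cases (113 adjusted over the list alone), with RPL9A (-1.66 ± 0.22). The group of cytosolic ribosomal proteins gave adjusted p = 1.5e-19, and adjusted p = 0.483 with an estimated correlation. Ribosome biogenesis genes fell in 63 of 91 cases (68 adjusted over the list alone; adjusted p = 5.6e-12, and adjusted p = 0.561 with an estimated correlation). Amino acid synthesis had 49 of 66 lower and 2 higher (50 and 2 adjusted over the list alone), with LYS9 (-2.34 ± 0.31). The amino acid synthesis group gave adjusted p = 1.9e-14, and adjusted p = 0.483 with an estimated correlation. Under cyclic loess the medians of ribosomal proteins and amino acid synthesis were -0.43 and -0.57, in place of -0.72 and -0.98. The transporters HXT1 (-5.44 ± 0.41) and HXT3 (-4.44 ± 0.14) fell, as did PHO12 (-3.50 ± 0.20), ANB1 (-3.03 ± 0.33) and IMD2 (-2.97 ± 0.34). HXT6, nearly identical to HXT7 and so uncertain, had 36 counts in galactose and 0 in glucose, at least 9.60-fold higher with a floor of 3 counts over the group.

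Cells of the brr6-1 strain were compared between media in the same way. All 12 GAL genes rose, with GAL2 (7.73 ± 0.48), GAL10 (7.51 ± 0.40), GAL1 (7.39 ± 0.41) and GAL7 (6.87 ± 0.27). The GAL regulon group gave adjusted p = 1.2e-62, and adjusted p = 0.0202 with an estimated correlation, where the call holds. All 32 respiratory chain genes rose, with CYC1 (4.43 ± 0.37) and NDE1 (3.15 ± 0.17). The respiratory chain group gave adjusted p = 1.9e-89, and adjusted p = 0.0207 with an estimated correlation, where the call holds. Of 15 TCA cycle genes, 14 rose, with SDH1 (2.79 ± 0.18) and SDH2 (2.75 ± 0.21). The TCA cycle group gave adjusted p = 1.2e-24, and adjusted p = 0.0202 with an estimated correlation, where the call holds. Of the glucose-repressed genes 22 of 29 rose, with JEN1 (5.95 ± 0.25) and SUC2 (3.63 ± 0.20). The group of glucose-repressed carbon genes gave adjusted p = 2.6e-36, and adjusted p = 0.0219 with an estimated correlation, where the call holds. Amino acid synthesis fell in 44 of 66 cases, with LYS9 (-2.83 ± 0.31) and HIS4 (-2.50 ± 0.40). The amino acid synthesis group gave adjusted p = 3.2e-22, and adjusted p = 0.286 with an estimated correlation. Purine synthesis fell in 12 of 16, with ADE17 (-3.15 ± 0.45). The purine synthesis group gave adjusted p = 9.7e-08, and adjusted p = 0.194 with an estimated correlation. Among the genes that fell were ANB1 (-5.11 ± 0.35), HXT3 (-4.71 ± 0.14), HXT1 (-3.41 ± 0.37) and AAC3 (-2.96 ± 0.17). General stress genes rose in 19 of 60 cases and fell in 2, with TMA10 (3.90 ± 0.19) and SOD2 (1.87 ± 0.22). The general stress response group gave adjusted p = 5.0e-06, and adjusted p = 0.306 with an estimated correlation. The interaction test above shows where the responses of the strains differed. In WT 2820 genes changed (1532 higher, 1288 lower) and in brr6-1 1008 (551 and 457). Library totals alone moved the median of all genes by 0.30 and 0.21, with 79.7% and 80.9% of calls higher instead of 54.3% and 54.7%. Leaving out WT glucose replicates A and B gave 1761 and 1548 genes in WT, and leaving out brr6-1 galactose replicates A and B gave 492 and 529 in brr6-1.

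Genes within 25 kb of a chromosome end were examined in both media, because chromosome ends lie at the nuclear envelope. In glucose 68 of 254 rose and 26 fell, with a median of 0.50 (adjusted p = 0.00111, and adjusted p = 0.295 with an estimated correlation). In galactose 31 rose and 37 fell, and the group was not shifted (median 0.12, adjusted p = 0.157), although genes within 15 kb were (adjusted p = 7.7e-04). Of those 130 genes 19 rose and 9 fell. Median abundance was 3.66 log2 CPM within 25 kb and 2.57 within 15 kb. Both ends of chromosome III are part of these sets. On that whole chromosome 133 of 159 tested genes rose in glucose and 125 in galactose. The sets were not tested without that chromosome, so its part in the shifts is not known.

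For the ChIP-seq, FLAG-tagged fragments that lack the membrane part were expressed from a galactose promoter on a plasmid in W303 cells. Brr6N is a part of Brr6 with a nuclear localisation signal, ΔC4N is that part without the putative zinc finger, and cells with the empty vector gave the background. Each construct had 2 FLAG precipitates (a and b) and 1 total extract. The deposited list holds 22 peaks of 40 to 3060 bp (R64), of which 21 name a gene and together name 30 genes. The authors' fold, signal of the precipitate over that of the total extract of the same construct, was above 1 in both Brr6N precipitates at 18 peaks. Mean folds ± SD (n = 2) at the highest peak, on chromosome IV from 1155680 to 1158740 beside HXT7, a high-affinity hexose transporter gene, were 6.99 ± 0.330 for Brr6N, 1.73 ± 0.134 for ΔC4N and 1.49 ± 0.244 for the vector. A second peak, listed for HXT7 and YDR341C (1153300 to 1154120), had 2.80 ± 0.0987, 1.64 ± 0.351 and 1.25 ± 0.00268. Of these genes, only YDR341C has its start within 1000 bp of that peak. At FUR4 and POA1 on chromosome II (282280 to 283780) the folds were 2.89 ± 0.0414, 1.3 ± 0.111 and 1.09 ± 0.224. At MNL2 and SHM2 on chromosome XII (257460 to 258920) Brr6N had 2.69 ± 0.0719 and the vector 1.04 ± 0.00929. HSP26 with RDH54 on chromosome II (381820 to 383380) had 2.20 ± 0.135 for Brr6N and 0.721 ± 0.0241 for the vector. The same values were, at SSA3 with ILS1 (84140 to 86000), 2.04 ± 0.137 and 0.822 ± 0.0441, and, at HSP30 with MAK31 and HTL1 on chromosome III (154820 to 156900), 2.01 ± 0.118 and 0.745 ± 0.0398. At STE2 with BST1 on chromosome VI (82400 to 84200) and at BRR6 with PDE1 and RAI1 on chromosome VII (36720 to 37620), ΔC4N was higher than Brr6N, with 2.51 ± 0.386 against 2.16 ± 0.0852 and 3.33 ± 0.195 against 2.14 ± 0.0211. The fragment plasmids carry BRR6 sequence that the empty vector lacks, so signal at the BRR6 peak cannot be told apart from plasmid DNA. MFA2 on chromosome XIV (352320 to 352440) had 1.62 ± 0.0338 for Brr6N and 1.68 ± 0.357 for ΔC4N.

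Both Brr6N folds lay above both vector folds at 19 of the 22 peaks, above both ΔC4N folds at 13 and above both other constructs at 13, while both ΔC4N folds lay above both vector folds at 12. These counts include peaks at genes of a-cells, at BRR6 and at the silent mating-type genes. At the 12 other peaks Brr6N was above the vector at 9 and above both other constructs at 9, while ΔC4N was above the vector at 3. The peak at AGA1 on chromosome XIV is among these 12 and counts toward the 9 and the 3. Its mean folds were 1.21 for Brr6N and 1.05 for ΔC4N. Both fragments were above the vector there and the mean vector fold was below 1, as at the a-cell peaks below. The 12 peaks were not counted without AGA1, so they may not be clear of the a-cell pattern. With 2 values against 2, 16.7% of peaks would show such an order of a pair of constructs in a stated direction by chance. The smallest two-sided exact permutation p is 0.333, so no peak was tested alone. That rate does not cover the order above both other constructs. It is also no yardstick for these counts, since the peaks were listed from the same data. In all, 8 peaks lie at genes of a-cells (STE2, MFA1, MFA2, STE6 and 4 at BAR1). Both fragments were above the vector at 8 of them. Brr6N was above ΔC4N at the 4 at BAR1 and ΔC4N above Brr6N at 2 (STE2 and STE6). The mean vector fold was below 1 at all of them, from 0.549 at STE6 to 0.757 at MFA2. At MFA1 the mean folds of Brr6N (0.941) and ΔC4N (0.982) were below 1 too. So was that of ΔC4N at the BAR1 peaks that start at 322500 (0.890) and 322840 (0.925).

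**Figure D3:**
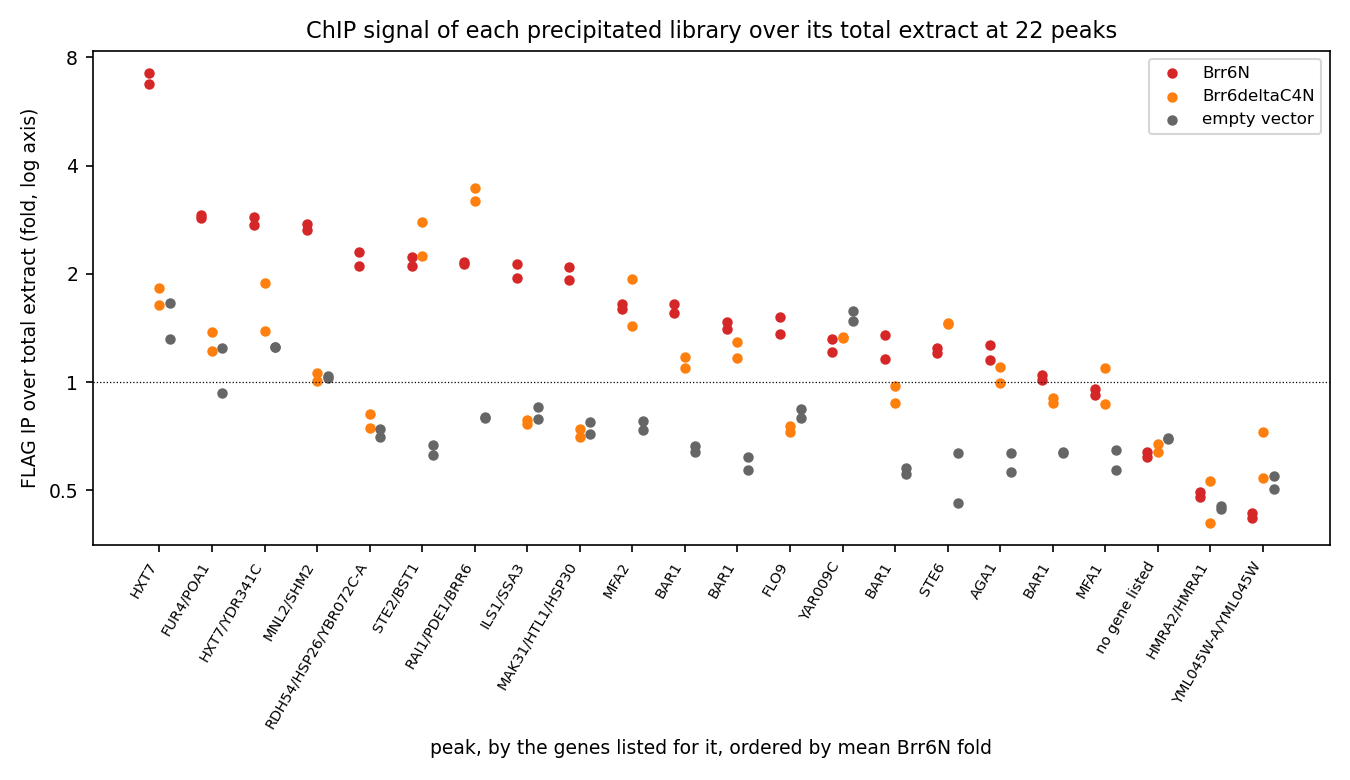
Fold of the FLAG precipitate over its total extract at 22 peaks, ordered by mean Brr6N fold, for 2 precipitates each of Brr6N, ΔC4N and the empty vector (points, log axis). HXT7 has the highest Brr6N fold (6.99), and at the a-cell genes both fragments stand above the vector.

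Peak genes were set against the RNA changes. Of 25 tested peak genes, 9 rose and 1 fell in glucose (40.0% changed, against 36.2% of other genes; Fisher's exact test, adjusted p = 0.682), and 6 rose and 3 fell in galactose (36.0% against 22.5%, adjusted p = 0.292). As a group they were shifted upward in both media (adjusted p = 4.6e-05 and 1.9e-04, and adjusted p = 0.0426 with an estimated correlation in both). Without the genes at the BRR6 peak and on chromosome III, tried after the data were seen, the adjusted p with the preset correlation was 0.136 in glucose and 0.852 in galactose. For the 16 genes listed at peaks where Brr6N was above both other constructs it was 0.0520 and 0.428. In galactose FUR4 rose (1.90 ± 0.16), HXT7 (-2.15 ± 0.21), HSP26 (-3.57 ± 0.26) and SHM2 (-1.23 ± 0.25) fell and SSA3 had 0.37 ± 0.13 (adjusted p = 0.0584). HXT7 is nearly identical to HXT6, so its values are uncertain in both media. In glucose HSP30, on chromosome III, rose (2.18 ± 0.29), and FUR4 and HXT7 had 0.34 ± 0.16 and 0.63 ± 0.27 (adjusted p = 0.125 and 0.0891). HSP30 had -0.31 ± 0.25 in galactose (adjusted p = 0.390). The ChIP cultures held galactose, so the glucose values are from an unlike medium. SHM2 (adjusted p = 0.0665) no longer passed without brr6-1 galactose replicate A. SHM2 (adjusted p = 0.0536) no longer passed without brr6-1 galactose replicate B.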

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

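The tests on the mating type of the ChIP cultures and on the zinc finger were chosen only after the result was seen.

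Effects of brr6-1 that differed between media were singled out by the interaction test of edgeR, which called 352 genes. Positive values mean that the log2 fold change was higher in galactose than in glucose. Among the genes named in the text, positive differences were PHO12 (3.12), SPL2 (2.88), PHO11 (2.19), CYC1 (1.87), FET3 (1.77), FUR4 (1.56), PHO84 (1.42), VTC3 (1.39), FTR1 (1.35), BRR6 (1.34), LEU1 (1.05) and RAI1 (0.82). Negative differences were OYE3 (-3.67), TDH1 (-3.66), SPG4 (-3.37), HSP26 (-3.24), GSY1 (-3.20), ADH2 (-3.17), HSP12 (-2.97), DAN1 (-2.86), HXT7 (-2.78), FIT3 (-2.67), HSP30 (-2.49), TSL1 (-2.41), TMA10 (-2.17), ANB1 (-2.08), ZRT1 (-2.00), PGM2 (-1.75), HXK1 (-1.74), PDR15 (-1.63), ENO1 (-1.59), GSC2 (-1.48), GAL3 (-1.44), ARN1 (-1.40), MET2 (-1.34), PHM8 (-1.32) and GPM1 (-0.85). Of the gene groups, those shifted upward in galactose relative to glucose were, with adjusted p, respiratory chain (1.7e-07), cytosolic ribosomal proteins (1.1e-08), ribosome biogenesis (1.6e-19), phosphate starvation (3.7e-07) and proteasome (0.0110). Those shifted downward were GAL regulon (0.0111), hexose transporters (0.0151), glucose-repressed carbon genes (5.3e-08), glycolysis (1.1e-10), general stress response (2.2e-36), heat shock and chaperones (0.020), hypoxia and membrane fluidity (3.2e-04), genes recruited to the nuclear periphery (4.8e-09), sulfur and methionine (0.0196), cell wall integrity (1.3e-09), pleiotropic drug resistance (3.2e-04) and meiosis and sporulation (0.00403). With an estimated correlation none of the 17 groups kept its call, and the smallest adjusted p among all groups was then 0.0681. CYC1 (adjusted p = 0.0563), FET3 (0.0584), hexose transporters (0.273), meiosis and sporulation (0.343), proteasome (0.0602) and sulfur and methionine (0.195) no longer passed without WT galactose replicate A. CYC1 (adjusted p = 0.0735), GAL regulon (0.116) and heat shock and chaperones (0.104) no longer passed without WT galactose replicate B. CYC1 (adjusted p = 0.207), FET3 (0.126), OYE3 (0.107), SPG4 (0.0875) and GAL regulon (0.109) no longer passed without WT glucose replicate A. CYC1 (adjusted p = 0.168), FET3 (0.0851), GSY1 (0.0518), HSP26 (0.0518), OYE3 (0.130), PHO11 (0.0527), SPG4 (0.0939), SPL2 (0.0678), TDH1 (0.0518) and heat shock and chaperones (0.0802) no longer passed without WT glucose replicate B. CYC1 (adjusted p = 0.151), FET3 (0.0749), OYE3 (0.0909) and heat shock and chaperones (0.0565) no longer passed without brr6-1 galactose replicate A. CYC1 (adjusted p = 0.112), FET3 (0.0762), OYE3 (0.0509) and proteasome (0.0690) no longer passed without brr6-1 galactose replicate B. CYC1 (adjusted p = 0.0504), GAL regulon (0.0832), heat shock and chaperones (0.204) and hexose transporters (0.174) no longer passed without brr6-1 glucose replicate A. Sulfur and methionine (adjusted p = 0.133) no longer passed without brr6-1 glucose replicate B. In DESeq2, CYC1 (adjusted p = 0.0715) no longer passed. With DESeq2 size factors, CYC1 (adjusted p = 0.0520) no longer passed. Under library totals alone, CYC1 (adjusted p = 0.0641) no longer passed. Under cyclic loess, OYE3 (adjusted p = 0.0636) and SPG4 (0.0619) no longer passed. With a replicate block, CYC1 (adjusted p = 0.0583) no longer passed. With robust empirical Bayes, CYC1 (adjusted p = 0.0790) and OYE3 (0.0577) no longer passed. Single genes outside the interaction paragraph of the report were not tried with libraries left out, and the count of all genes fell to 3 without WT glucose replicate B and 26 without WT glucose replicate A. No cause of these differences was tested.

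Signal in the total extracts, which the comparisons of folds use only as a divisor, stood out at 2 peaks. At the silent mating-type genes HMRA1 and HMRA2 it was 2.30 times that of the vector in Brr6N and 2.23 times in ΔC4N, relative to the other 20 peaks. At the BRR6 peak, where the fragment plasmids carry BRR6 sequence that the empty vector lacks, the ratios were 2.07 and 1.75. Before that scaling the other peaks ran from 0.790 to 1.66 in Brr6N and from 0.779 to 1.15 in ΔC4N. There was 1 total extract per construct, so these ratios have no replicate check.

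Peaks at genes that only a-cells express were weighed as a pattern, since the labels give the ChIP strain as MATα. Whether binding there needs the zinc finger stays open. Both Brr6N folds exceeded both ΔC4N folds at 4 of the 8 peaks, all at BAR1, and lay below them at 2, at STE2 and STE6, and a comparison with the vector culture rests on its mating type. A difference of mating type between the fragment cultures and the vector culture remains open and is a candidate explanation, as such cells would carry a second copy of the a1 and a2 sequences and the lower ratio at those genes was 2.23. Binding of both fragments to these genes remains open as well, and was not tested apart from the mating type.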

How the results depend on the processing

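Leaving out chromosome III genes, leaving out the features missing from the gene table, cyclic loess scaling and leaving out the peak genes at BRR6 and on chromosome III were tests chosen only after the data were seen. Other scalings, filters and tests moved counts of changed genes by at most 1.5 times, except that DESeq2 called 606 genes for the difference between media. With 1 library left out, counts fell or rose and ran from 516 to 2400 in glucose, 423 to 1801 in galactose, 1548 to 2931 between media in WT, 492 to 924 in brr6-1 and 3 to 816 for the difference. The lone library of such a group is assumed to vary like the others. No label ties the letters A and B to a shared day or batch. Their deviations correlated between groups at -0.17 to 0.29, highest between the brr6-1 groups, which cannot exclude pairing by letter. A replicate block over the letters called 2359, 1545, 2820, 1018 and 306 genes in the same order.

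With an estimated correlation 1, 2, 3, 5 and 0 gene groups were shifted in these 5 comparisons, and with groups tested alone 5 were shifted for the difference; the cause was not tested. For amino acid synthesis, the difference between media ran from an adjusted p of 5.0e-06 to 0.959 with 1 library left out and turned the other way without brr6-1 glucose replicate A (adjusted p = 0.00162); the cause was not tested. Of 1426 values for groups, 1225 kept the status of the call, where a change of sign in a value that passed neither way counted as the same. Of 2549 values for named genes, 2418 did so, 114 lost the call and 17 gained one.

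The correlation between media was 0.548 with at least 100 counts in each of 2 libraries and ran from 0.447 to 0.707 with 1 library left out. Chromosome-end genes were no longer shifted in glucose with an estimated correlation (adjusted p = 0.295), and were shifted in galactose within 15 kb (adjusted p = 7.7e-04). The shift of peak genes in galactose had an adjusted p of 0.0538 for genes within 1000 bp. Without the genes at BRR6 and on chromosome III it had 0.852, and that in glucose 0.136, with fewer genes tested. The cause was not tested otherwise. A comparison of peak overlap by a larger shared part was not run, since there is 1 peak list, and neither was removal of non-coding features, since the files hold open reading frames.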

Other observations

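The tests on the LEU2 marker, on the trend with abundance and on the share of chromosome III counts were chosen only after the result was seen.

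Genes of amino acid synthesis shifted downward as a group in both media, and some single genes of other groups fell. Among amino acid and nitrogen genes, LEU1 fell (-3.00 ± 0.19 in glucose and -1.95 ± 0.19 in galactose), as did GDH1 (-2.02 ± 0.21) and BAT1 (-1.70 ± 0.15) in glucose and GDH1 (-2.00 ± 0.21), BAT1 (-1.98 ± 0.15) and GLN1 (-1.68 ± 0.16) in galactose. The LEU2 and HIS3 markers of the allele also differ between the strains, so these falls cannot be assigned to the brr6-1 change alone. The synthesis group as a whole shifted downward in glucose (adjusted p = 1.3e-04, and adjusted p = 0.571 with an estimated correlation) and galactose (adjusted p = 5.7e-04, and adjusted p = 0.579 with an estimated correlation), and in glucose its adjusted p was 0.690 without brr6-1 glucose replicate A. The histone genes HHT1 (-1.01 ± 0.16) and HHT2 (-0.92 ± 0.18) fell in glucose and HHT2 (-1.17 ± 0.18) and HHT1 (-0.79 ± 0.16) in galactose, while HHF1 had -0.08 ± 0.15 and 0.07 ± 0.15 (adjusted p = 0.694 and 0.760), and the group was not shifted (adjusted p = 0.122 and 0.214). In the purine group ADE17 (-1.61 ± 0.43) and ADE12 (-1.57 ± 0.34) fell in galactose. Purine synthesis shifted downward in galactose (adjusted p = 5.7e-04, and adjusted p = 0.409 with an estimated correlation) and in glucose (adjusted p = 0.0110, and adjusted p = 0.539 with an estimated correlation), where its adjusted p was 0.322 without brr6-1 glucose replicate A. Tested alone, the purine group had 0.107 in glucose and 0.0517 in galactose, and amino acid synthesis 0.147 and 0.163 (adjusted p). Both groups lie over 8 log2 CPM (medians 8.56 for amino acid and 8.45 for purine synthesis), where genes had a negative median in glucose. Under cyclic loess their medians in glucose were -0.17 and -0.26, in place of -0.33 and -0.49. ZRT1 (-2.22 ± 0.26), a zinc transporter, fell in galactose and HAC1 (-1.48 ± 0.17), the regulator of the unfolded protein response, fell in glucose. Their groups were not shifted there, with an adjusted p of 0.191 for the zinc regulon in galactose and 0.0540 for the unfolded protein response in glucose. ADE17 (adjusted p = 0.112) no longer passed without WT galactose replicate B. ADE12 (adjusted p = 0.0835), ADE17 (0.176) and HHT1 (0.0796) no longer passed without brr6-1 galactose replicate A. ADE12 (adjusted p = 0.0586) and ADE17 (0.0781) no longer passed without brr6-1 galactose replicate B. With robust empirical Bayes, ADE17 (adjusted p = 0.0740) no longer passed.

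Genes of chromosome III were higher in brr6-1 as a pattern. Their share of gene counts was 4.25 ± 0.492% (SD, n = 4) in brr6-1 and 2.32 ± 0.170% in WT (exact permutation test over the 36 splits within medium, two-sided p = 0.0556, the smallest it can give). A local effect of the LEU2 marker was argued against, since genes over 50 kb from LEU2 had medians of at least 1.03, and so was a trend with abundance, since the excess over genes of like abundance was at least 0.97. An extra copy of the chromosome in the brr6-1 strain remains open and is a candidate explanation, as medians of the 6 segments of 50 kb with at least 10 tested genes ran from 0.85 to 1.32 over both media. The last segment, with 9 genes, had 1.45 in glucose and 1.58 in galactose. DNA of the RNA strains was not analysed here, and no other biological explanation was tested.

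Genes under 2 log2 CPM were higher in brr6-1 as a further pattern. They took 0.0724 and 0.0701% of gene counts in WT glucose, 0.189 and 0.149% in brr6-1 glucose, 0.165 and 0.0999% in WT galactose and 0.227 and 0.223% in brr6-1 galactose. Unequal depth was argued against, as their median in glucose was 1.22 after all libraries were thinned to the smallest. Reads from outside annotated genes remain open. In WT galactose, library A had 37.3% of its reads outside genes against 26.7% in library B, and these genes were higher by 0.89 log2 in A relative to abundant genes, but that rests on a single pair of libraries. Other libraries do not all go one way. WT glucose A and B had the fewest reads outside genes (23.4 and 24.1%) and the smallest shares of counts in these genes. In brr6-1 galactose A both the reads outside genes (37.5%) and that share were above WT galactose A. In contrast, brr6-1 glucose A (28.5%) and brr6-1 galactose B (36.2%) had fewer reads outside genes than WT galactose A and yet a larger share. In brr6-1 glucose B (29.2% outside genes) that share was below WT galactose A. An effect of the genotype was not tested apart from this.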
